A study of Mus musculus with 383 samples.

How the data were processed

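Single cells were sorted from mouse skin squamous cell carcinomas and sequenced by Smart-seq2, a method that amplifies full-length cDNA from each cell and adds no molecular identifiers. Per the labels, the tumours arose in genetically engineered mice with an Lgr5-driven Cre recombinase and floxed p53, in which recombined cells carry YFP, and YFP-positive cells were sorted as Epcam-positive or Epcam-negative. The labels describe 383 wells: 70 Epcam-positive single cells, 310 Epcam-negative single cells, 1 Epcam-positive and 1 Epcam-negative well set up with 0 cells, and 1 Epcam-negative well set up with 50 cells. A spike-in RNA mix was added to the wells at a single dilution.

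The values deposited by the authors are raw read counts per gene and per spike-in in each well. Per the submitters' processing notes, reads of 50 bases were trimmed with cutadapt 1.13, aligned with STAR 2.5.2b to the mouse genome build GRCm38 and counted with HTSeq 0.6.0. The annotation release and the strand setting of the counting are not given in the sources used here, so values of genes that overlap another gene, or that share sequence with a close relative such as Krt6a and Krt6b, carry an uncertainty that was not measured. The table held 49585 genes and 92 spike-ins. Of the gene identifiers, 49326 were given a symbol from the GENCODE vM21 annotation, matched without the version suffix, and 259 were not matched. With the version, 43749 matched. Gene positions are those of that annotation. No wells had identical counts.

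A cell was kept with at least 100000 reads in genes, at least 2000 genes with a read, at most 20% of gene reads from mitochondrial genes, and spike-in reads at most 50% of gene plus spike-in reads. This kept 62 Epcam-positive and 263 Epcam-negative cells and left out 8 and 47. Reads were summed over the kept cells of a population and scaled to counts per 1000000 gene reads (CPM). Ratios are log2 of (CPM in Epcam-negative + 1) over (CPM in Epcam-positive + 1), so that a positive value means a higher level in the Epcam-negative population. For shares of cells, each cell was thinned at random to 100000 gene reads and a gene was called present at 5 or more of them, which corresponds to 50 CPM. RNA content was taken as gene reads per spike-in read.

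The labels name no animal or culture. Each sorted population was therefore treated as 1 sample, cells were not taken as replicates, and no test between populations and no count of changed genes was made. Intervals are exact 95% intervals: Poisson for CPM, Clopper-Pearson for shares of cells and conditional binomial for ratios. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. For a gene with no read in a population, a lower bound of the fold was computed with 3 reads over that population. The Epcam-positive cells sat in plate rows A to C and the Epcam-negative cells in rows D to P, so that population and plate position cannot be told apart. Values were also computed in plate columns 1 to 12 and 13 to 24, each of which held cells of both populations.

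Gene lists were fixed for epithelial genes (junction and adhesion, keratins, transcription and splicing regulators), mesenchymal genes (matrix, EMT transcription factors, cytoskeleton and surface), the surface markers Itgav, Itgb3 and Vcam1, hair follicle lineage, TGF-beta, Wnt, S phase, G2 and M phase, hypoxia and glycolysis, interferon, MHC class I, immediate early genes, cytokines, terminal differentiation, hemidesmosomes, matrix proteases, p53 targets, and markers of immune, endothelial, dermal fibroblast, pericyte, melanocyte and erythroid cells. A list member was measured with at least 10 CPM in either population. The median of each list was set against 10000 random lists of the same size matched on mean expression, and its percentile among them is given. Named genes are, per list, the 2 to 4 with the largest absolute ratio and any member that goes against its list's median by 2-fold or more. Beyond the lists, they are the 12 highest and the 12 lowest ratios among genes with at least 50 CPM in the higher population, present in at least 30% of its cells, with the same direction in both sets of plate columns, and without predicted, mitochondrial or ribosomal protein genes. Epcam, Krt14, Vim, Trp53, Itgav, Itgb3 and Vcam1 are always named. Results for some genes that these rules name are left out of the text.

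Clusters were made on log1p of CPM divided by 100 over the 2000 most variable genes, with 20 principal components, 15 neighbours and Leiden clustering at resolution 0.5. No doublet caller was used, since wells were filled by single-cell sorting with a doublet gate. The groups, lists, filters, named-gene rule and most alternatives were chosen before the data were examined. Alternatives were no filter on cells, a stricter filter (250000 reads, 3000 genes, 10% mitochondrial, 25% spike-in), the mean of each cell's CPM, TMM, median-of-ratios and spike-in scaling, pseudocounts of 0.1 and 10 CPM, each set of plate columns, the 50-cell well in place of the Epcam-negative cells, no filter on low list members, other presence rules, RNA content without mitochondrial genes or from summed reads, and other cluster resolutions and gene numbers. Leaving out the Epcam-negative cells of cluster 0, leaving out the Epcam-positive cell with most Col1a1 reads, and clustering without the genes at the start of chromosome 9 or without those of at least 500 CPM in Epcam-positive cells, were added after the data were seen.

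The comparison of Epcam-negative with Epcam-positive was tested on simulated data with 8874 genes. Among them, 100 genes made 4-fold higher were recovered with a median log2 ratio of 1.92, and 100 genes made 4-fold lower with -1.91. Of 8664 genes left as they were, 0% differed 2-fold or more. This share holds only for the spread between cells that was simulated, and is no false 2-fold rate for the kept cells. Among these, reads of some genes lay mostly in a single cell, such as 56.9% of the Epcam-positive reads of Mmp3. Of 5000 simulated counts with a known mean, 96.0% had that mean within the 95% Poisson interval. Over 20 simulated lists of 30 unaltered genes, percentiles ran from 0.17 to 99.1, so a percentile near 0 or 100 for a short list is no test. A planted block of 10 neighbouring genes made higher by 3 on the log2 scale was found with 9 of its genes in the highest window.

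Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors alone.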

Results

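Transcriptomes of single tumour cells from a mouse model of skin squamous cell carcinoma were measured as read counts per gene. The tumours were induced in Lgr5-expressing cells, a hair follicle stem cell lineage, by engineered alleles that include a floxed p53, and recombined cells were traced by YFP. Cells were sorted by Epcam, a surface adhesion protein of epithelia, into an Epcam-positive population (70 cells, 8 of them left out) and an Epcam-negative population (310 cells, 47 of them left out). Labelled cells had from 2202 gene reads in the Epcam-positive and from 936 in the Epcam-negative population. Kept Epcam-positive cells had 109743 to 730528 gene reads (median 413142), and kept Epcam-negative cells 104330 to 900492 (median 414731), which sum to 24840769 and 107313931 reads. The median number of genes with a read was 6996 in Epcam-positive and 6584 in Epcam-negative cells, and the median mitochondrial share 6.32% and 4.36%. There was 1 sample per population and no replicate, so no test between them was made, and population cannot be told apart from plate position (rows A to C for Epcam-positive and D to P for Epcam-negative cells). Intervals are 95% and cover counting error only, and levels are in CPM, with log2 ratios of Epcam-negative over Epcam-positive.

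The comparison of the populations addresses how tumour cells without Epcam at the surface differ in transcription from those with it, in the course of an epithelial to mesenchymal transition (EMT). Epithelial genes were lower in Epcam-negative cells almost throughout. Epcam itself, on chromosome 17 from 87635979 to 87651129 (ENSMUSG00000045394.8) of GRCm38, was at 1069 CPM in Epcam-positive and 22.7 CPM in Epcam-negative cells, a log2 ratio of -5.49 (-5.55 to -5.44). Cdh1, the E-cadherin of adherens junctions, was at 202.01 and 3.90 CPM, and Cldn4, a tight junction claudin, at 280.5 and 5.48 CPM. All 14 measured junction genes were higher in Epcam-positive cells, 13 of them 2-fold or more, with a median of -2.85. Of 10 keratins, which form the intermediate filaments of epithelia, 9 were higher in Epcam-positive cells and 8 by 2-fold or more, with a median of -3.05. Krt6b was at 335 and 5.51 CPM and Krt17 at 5391 and 227.1 CPM, whereas the simple-epithelium keratin Krt8 was at 81.04 and 85.1 CPM. All 11 regulators were higher in Epcam-positive cells, 10 by 2-fold or more, with a median of -2.94. Among these, the transcription factor Ehf was at 125.4 and 2.06 CPM, the splicing factor Esrp1 at 112.7 and 4.81 CPM, and the transcription factor Grhl2 at 41.4 and 2.42 CPM. Over the 35 measured epithelial genes the median was -2.86, below all 10000 random lists, and 31 were 2-fold or more higher in Epcam-positive cells. The medians of the lower and upper interval ends of the 35 genes were -2.90 and -2.84, which leave out the spread between genes. Without the Epcam-negative cell with most of its reads, the Epcam-negative level was 14.7 CPM for Epcam, 0.917 CPM for Cldn4, 2.57 CPM for Krt6b and 0.835 CPM for Ehf, and Krt6b was at 207.3 CPM without such a cell in Epcam-positive cells.

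Krt14, a basal keratin on chromosome 11 from 100203162 to 100207548 (ENSMUSG00000045545.8), was at 13311 CPM in Epcam-positive and 1836 CPM in Epcam-negative cells, a log2 ratio of -2.86 (-2.86 to -2.85). The median Epcam-negative cell had 31.97 CPM of Krt14, with an upper quartile of 1027 CPM, against a median of 11597 CPM in Epcam-positive cells. The Epcam-negative level of epithelial genes rested in part on 18 of the kept cells that fell into a cluster with most Epcam-positive cells. Without them Krt14 was at 893 CPM, Epcam at 1.38 CPM, and the epithelial median was -3.90.

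Mesenchymal genes were higher in Epcam-negative cells, with fibrillar collagens and their crosslinking enzymes at the top. Col1a1, a chain of type I collagen, was at 15.98 CPM in Epcam-positive and 2593 CPM in Epcam-negative cells, and Col3a1 at 31.2 and 4756 CPM. Lox, which crosslinks collagen, was at 5.56 and 739 CPM, and Col1a2, the other chain of type I collagen, at 45.5 and 4692 CPM. All 17 matrix genes were higher in Epcam-negative cells, 16 by 2-fold or more, with a median of 5.46. Among 6 EMT transcription factors, which repress epithelial genes or activate mesenchymal ones, 5 were 2-fold or more higher in Epcam-negative cells, with a median of 3.93. Snai1 was at 0.725 and 58.5 CPM, Zeb2 at 1.37 and 72.04 CPM, and Zeb1 at 1.25 and 48.6 CPM. In the 50-cell well Snai1 had 0 reads, which allows up to 23.8 CPM, whereas Zeb2 had 14 reads and Zeb1 10. A single Epcam-positive cell held 54.7% of the Col1a1 reads of its population, and without it the Epcam-positive level was 7.33 CPM for Col1a1, 13.07 CPM for Col3a1, 3.14 CPM for Lox, 18.04 CPM for Col1a2 and 0.652 CPM for Zeb2, and the median of the matrix genes was 5.71. Without the cell with most of its reads Zeb1 was at 0.780 CPM. Snai2, the related Slug factor, had the opposite direction, at 98.9 CPM in Epcam-positive and 16.2 CPM in Epcam-negative cells, and was present in 50.0% and 11.4% of cells.

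All 12 genes for mesenchymal cytoskeleton and surface proteins were 2-fold or more higher in Epcam-negative cells, with a median of 3.47. Vim, the intermediate filament of mesenchymal cells, on chromosome 2 from 13573927 to 13582826 (ENSMUSG00000026728.9), was at 592 and 5809 CPM, a log2 ratio of 3.29 (3.27 to 3.32). The growth factor receptor gene Pdgfrb was at 1.01 and 169.3 CPM and the cadherin gene Cdh11 at 3.90 and 254.5 CPM. Cdh2, the N-cadherin, was at 0.0805 CPM from 2 reads in Epcam-positive cells and at 30.1 CPM in Epcam-negative cells. Fap, a fibroblast protease gene, had 0 reads in Epcam-positive cells. With 3 reads over the population as the floor, Fap was at least 132.8-fold higher in Epcam-negative cells. That bound covers counting error only, and the Fap reads lay in 48 Epcam-negative cells. Over the 35 measured mesenchymal genes the median was 4.46, the same with Fap at its bound and above all 10000 random lists. Of them, 33 were 2-fold or more higher in Epcam-negative cells. The medians of the lower and upper interval ends of the 35 genes were 4.16 and 4.68, which leave out the spread between genes. With a pseudocount of 10 CPM the list median was 3.28. Without the Epcam-positive cell with most of its reads, Pdgfrb was at 0.448 CPM and Cdh11 at 2.12 CPM in Epcam-positive cells.

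**Figure D1:**
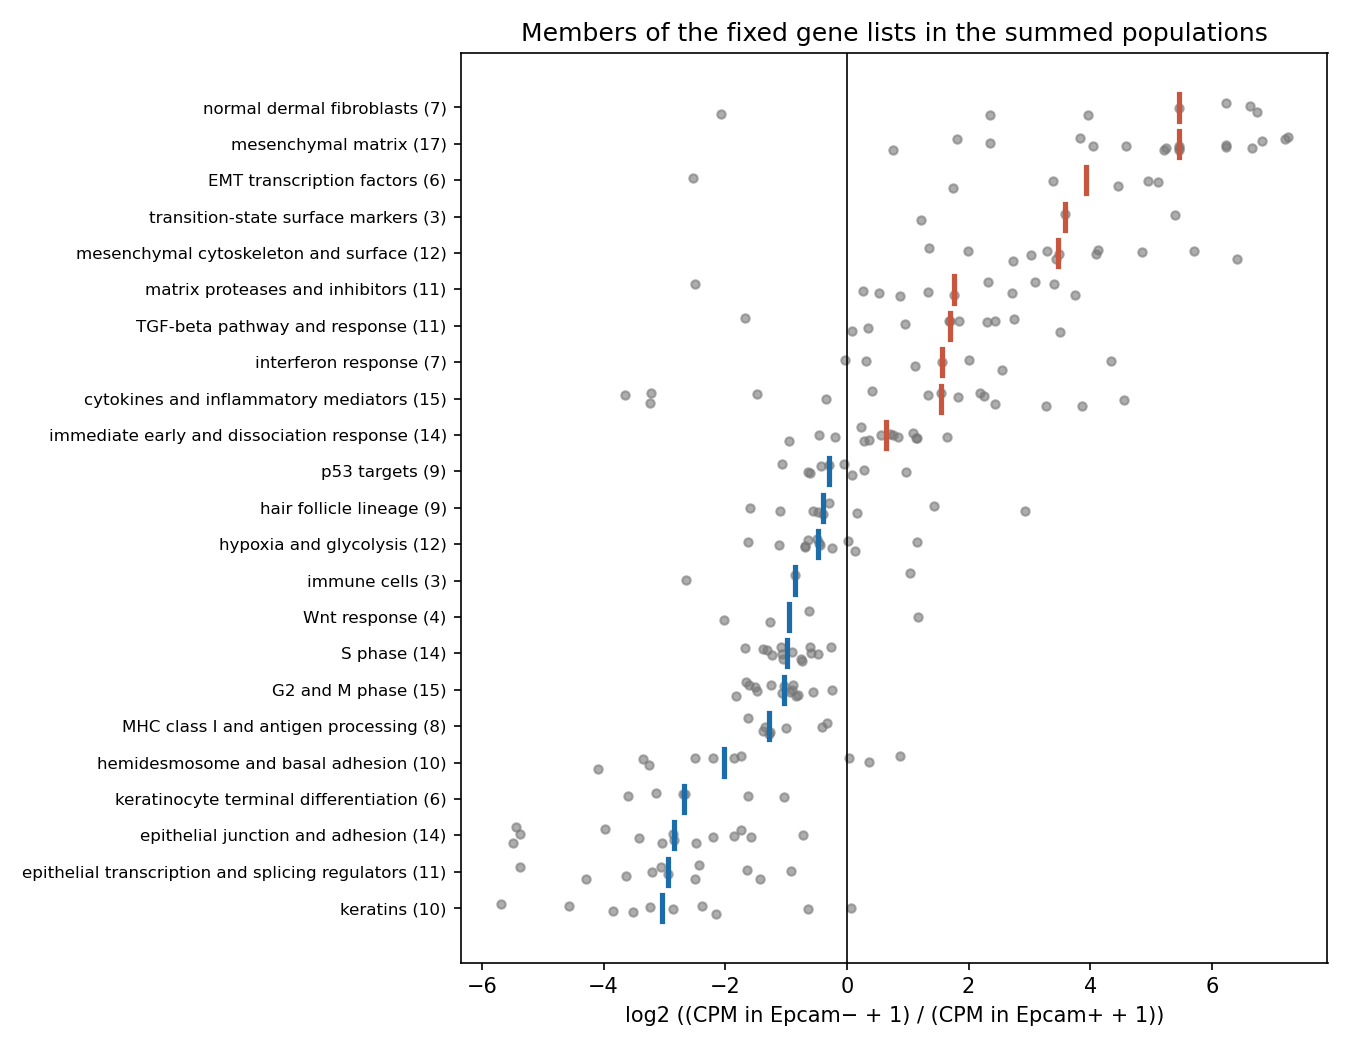
Log2 CPM ratios of Epcam-negative over Epcam-positive cells for the measured members of each gene list with at least 3 of them, with 1 point per gene and a bar at each list's median. Epithelial lists sit to the left (median -2.86 over 35 genes) and mesenchymal lists to the right (median 4.46 over 35 genes), with Krt8 and Snai2 apart from their lists.

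Beyond the lists, the genes with the lowest ratios were Gpx2, Il24, Arhgef16, Sostdc1, Prss22, Epcam, Sult2b1, Cldn4, Cdh1, Ehf, S100a14 and Fam89a, among 1960 genes that met the criteria for Epcam-positive cells. Gpx2, a glutathione peroxidase of epithelia on chromosome 12 from 76792333 to 76795554 (ENSMUSG00000042808.7), was at 186.99 CPM in Epcam-positive and 0.103 CPM in Epcam-negative cells, a log2 ratio of -7.41 (-7.48 to -7.31). Il24, a cytokine of the IL-10 family on chromosome 1 from 130882074 to 130887454 (ENSMUSG00000026420.16), was at 338 and 1.75 CPM. Sostdc1, a secreted antagonist of BMP and Wnt signals, was at 311 and 4.29 CPM, and S100a14, a calcium-binding protein of epithelia, at 353 and 8.98 CPM. The highest ratios, among 1434 genes that met the criteria for Epcam-negative cells, were those of Col1a1, Col3a1, Loxl1, Nrep, Col6a3, Lox, Adamts2, Aspn, Sfrp2, Col1a2, Mfap5 and Ccdc80. Col1a1, on chromosome 11 from 94936224 to 94953042 (ENSMUSG00000001506.10), had a log2 ratio of 7.25 (7.12 to 7.39). Col3a1, on chromosome 1 from 45311538 to 45349706 (ENSMUSG00000026043.18), had 7.21 (7.11 to 7.31). Nrep was at 4.31 and 624 CPM, the small proteoglycan gene Aspn at 4.67 and 619.9 CPM, and Sfrp2, a secreted modulator of Wnt signals, at 1.29 and 236.7 CPM. Without the Epcam-positive cell with most of its reads, Il24 was at 221.7 CPM, Nrep at 2.54 CPM, Aspn at 1.75 CPM and Sfrp2 at 0.287 CPM there, and without such an Epcam-negative cell Gpx2 was at 0.0562 CPM and Il24 at 1.132 CPM.

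Trp53, the floxed tumour suppressor, on chromosome 11 from 69580359 to 69591873 (ENSMUSG00000059552.13), was at 25.2 and 18.4 CPM, a log2 ratio of -0.43 (-0.56 to -0.31), and had -0.90 in plate columns 1 to 12 and 0.14 in columns 13 to 24. Counts cover whole genes, so they do not show whether the floxed part of Trp53 was lost. Among 9 p53 targets the median was -0.30, at percentile 25.3 of random lists. The cell cycle inhibitor Cdkn1a was at 541 and 258.96 CPM, and Trp53inp1 at 15.5 and 31.5 CPM.

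The genes for 3 surface proteins used to part Epcam-negative tumour cells into subpopulations were higher in Epcam-negative cells. Vcam1, a cell adhesion molecule on chromosome 3 from 116109949 to 116129688 (ENSMUSG00000027962.14), was at 2.46 and 145.07 CPM, a log2 ratio of 5.40 (5.13 to 5.67), with 0.862 CPM in Epcam-positive cells without the cell that held most of its reads. Itgav, the integrin alpha V (CD51) on chromosome 2 from 83724397 to 83806916 (ENSMUSG00000027087.11), was at 68.1 and 159.96 CPM, a log2 ratio of 1.22 (1.15 to 1.29). Itgb3, the integrin beta 3 (CD61) on chromosome 11 from 104608000 to 104670476 (ENSMUSG00000020689.4), was at 0.0805 CPM from 2 reads and at 12.05 CPM, a log2 ratio of 3.59 (3.33 to 3.69). The median of the list was 3.59, at percentile 99.7. Of the kept Epcam-negative cells, 22.8% (17.9% to 28.4%) had none of the 3 transcripts present, 42.2% had 1, 31.6% had 2 and 3.42% had all 3. Of 62 kept Epcam-positive cells, 32 (51.6%, 38.6% to 64.5%) had none, 29 had 1, 1 had 2 and 0 had all 3, and that 0 allows up to 5.78%. Vcam1 and Itgav were present together in 82 Epcam-negative cells (31.2%) and in 1 Epcam-positive cell. These shares follow transcripts, not the surface proteins, and the share with none was 6.84% with a presence rule of 1 read and 57.8% with 20 reads.

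Epithelial and mesenchymal transcripts occurred together in single cells of both populations. Krt14 and Vim were both present in 47.1% of Epcam-negative cells (40.99% to 53.4%) and in 30 of 62 Epcam-positive cells (48.4%, 35.5% to 61.4%). The product of the single shares was 48.1% in Epcam-negative and 48.4% in Epcam-positive cells. Vim was present in 98.1% of Epcam-negative and Krt14 in 100% of Epcam-positive cells, so each share follows the other gene alone. Among the cells with both, Epcam was present in 6.45% of the Epcam-negative cells (8 cells) and in 29 of 30 Epcam-positive cells (96.7%). Among the rest, 50.95% of Epcam-negative cells had Vim without Krt14 and 1.90% had Krt14 without Vim. Of the other Epcam-positive cells, 32 (51.6%) had Krt14 without Vim. Vim levels in the Epcam-positive cells were low, with a median cell at 47.3 CPM against 5470.4 CPM in Epcam-negative cells. Carry-over of Vim reads into Epcam-positive cells was not tested.

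Partners of these genes differed in how often they were shared. Krt14 and Col1a1 were both present in 44.5% of Epcam-negative cells and in 3 Epcam-positive cells (4.84%). Krt5, the partner of Krt14 in basal cells, was present with Vim in 66 Epcam-negative cells (25.1%), and Trp63, the transcription factor p63 of basal epithelium, in 38 (14.4%). Krt14 was present with Zeb1 in 33 Epcam-negative cells (12.5%), whereas Zeb1 was present in 0 Epcam-positive cells. In Epcam-negative cells the products of the single shares were 46.6% for Krt14 and Col1a1, 26.5% for Krt5 and Vim, 15.7% for Trp63 and Vim, and 16.04% for Krt14 and Zeb1. For comparison, Col1a1 was present in 4.84% of Epcam-positive cells, and the genes abundant in Epcam-positive cells Krt17, Dsp and Krt5 in 13.7%, 26.6% and 26.996% of Epcam-negative cells, all at 100000 thinned reads per cell, with median depths before thinning of 413142 and 414731 gene reads. With 1 read or more and no thinning, Krt14 had a read in 99.6% of Epcam-negative and Vim in 95.2% of Epcam-positive cells, as did Col1a1 in 74.2% of Epcam-positive cells, so a single read is not taken as expression. With 20 thinned reads the shares with Krt14 and Vim were 33.5% and 35.5%.

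**Figure D2:**
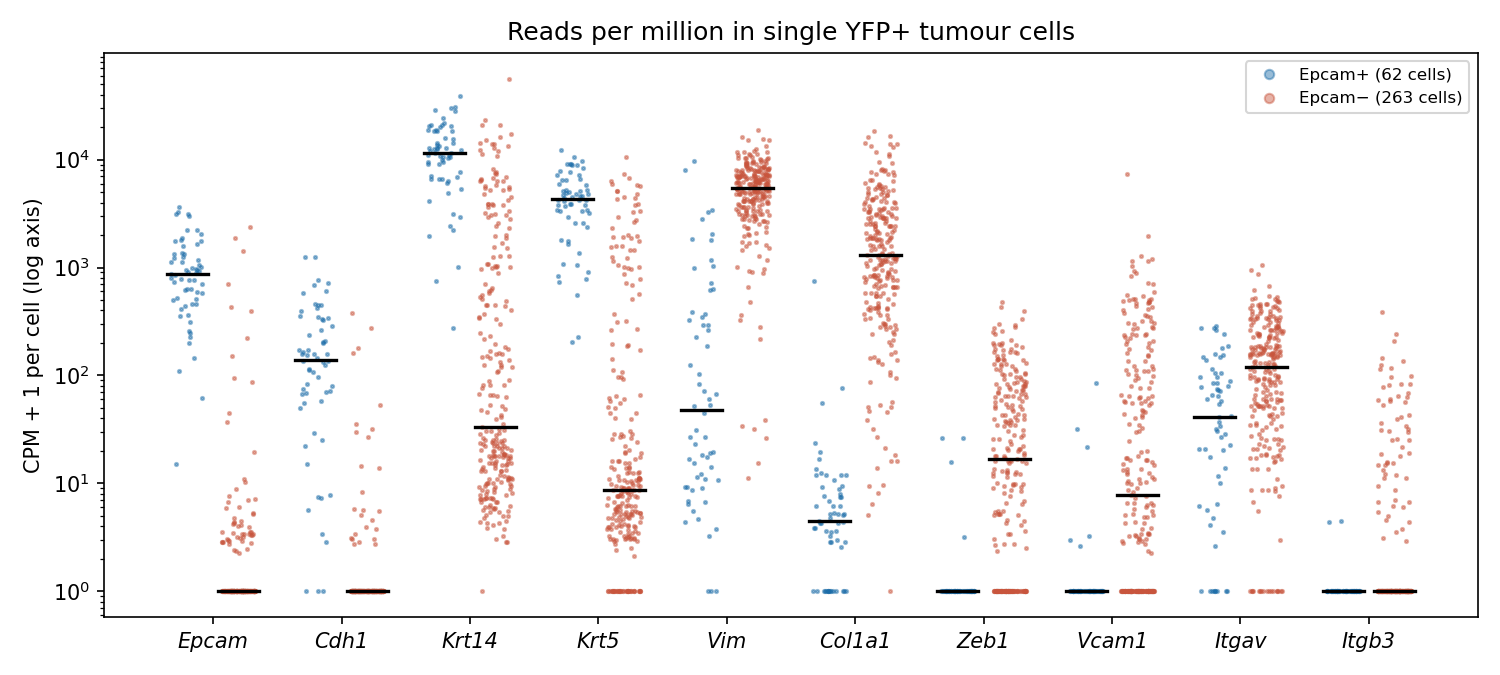
Levels of 10 marker genes in each kept cell, as CPM + 1 on a log axis, for the Epcam-positive and Epcam-negative populations, with 1 point per cell and a bar at the median. The median Krt14 level was 11597 CPM in Epcam-positive and 31.97 CPM in Epcam-negative cells, and the median Vim level 47.3 and 5470.4 CPM.

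**Figure D3:**
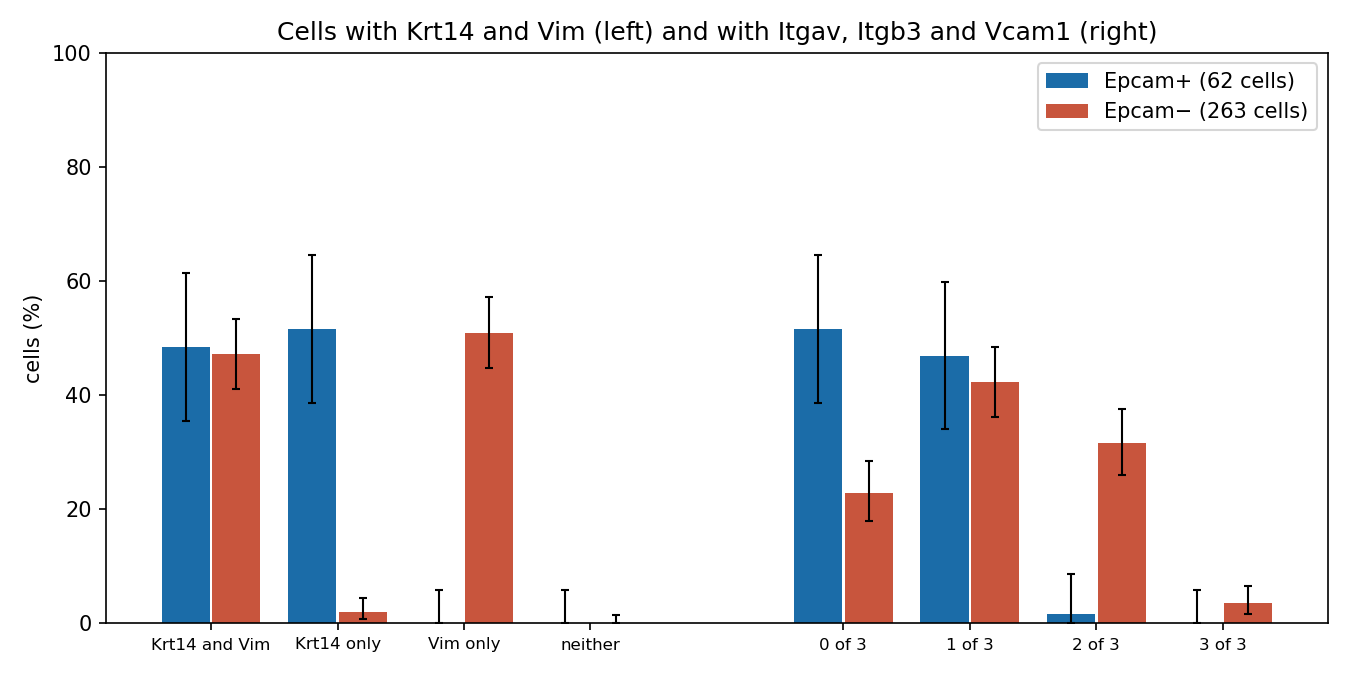
Percent of kept cells of each population (bars) with Krt14 and Vim together, singly or not at all, and with 0 to 3 of Itgav, Itgb3 and Vcam1, with exact 95% intervals that cover counting error only. Krt14 with Vim stands at 48.4% of Epcam-positive and 47.1% of Epcam-negative cells, and none of the 3 surface genes at 51.6% and 22.8%.

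Genes of the cell cycle were lower in Epcam-negative cells. All 14 S phase genes were higher in Epcam-positive cells, 7 by 2-fold or more, with a median of -0.98 at percentile 0.03, and all 15 genes of G2 and M phase, 8 by 2-fold or more, with a median of -1.03 at percentile 0. Ung, a DNA repair glycosylase, was at 12.9 and 3.34 CPM, Uhrf1, which maintains DNA methylation, at 27.9 and 10.1 CPM, Birc5, the mitotic protein survivin, at 164.5 and 45.8 CPM, and Cdc20, an activator of the anaphase-promoting complex, at 134.5 and 41.8 CPM. Mki67 or Top2a, proliferation markers, were present in 20 of 62 Epcam-positive cells (32.3%, 20.9% to 45.3%) and in 42 of the Epcam-negative cells (15.97%, 11.8% to 21.0%). The median of gene reads per spike-in read was 221.1 in Epcam-positive (quartiles 105.6 and 290.9) and 157.2 in Epcam-negative cells (83.9 and 245.8), a ratio of 0.711.

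Genes of keratinocyte differentiation, and most of those of attachment to the basement membrane, were likewise lower in Epcam-negative cells. All 6 measured terminal differentiation genes were 2-fold or more higher in Epcam-positive cells, with a median of -2.68 at percentile 0.02. Krtdap, a secreted keratinocyte protein, was at 735.5 and 60.1 CPM, and Sprr2d, a cornified envelope precursor, at 16.9 and 1.03 CPM (92.9% of its Epcam-positive reads in 3 cells, and 7.11 or 0.0748 CPM without the cell with most reads), though in the 50-cell well Sprr2d and Sprr1b were above the Epcam-positive level. Of 10 hemidesmosome and basal adhesion genes, 7 were 2-fold or more higher in Epcam-positive cells, with a median of -2.03 at percentile 0. The other 3 were higher in Epcam-negative cells, 0 of them by 2-fold or more. The laminin chains Lamb3 and Lama3 were at 305.5 and 411 CPM in Epcam-positive and at 16.99 and 39.3 CPM in Epcam-negative cells. All 8 MHC class I and antigen processing genes were higher in Epcam-positive cells, 6 by 2-fold or more, with a median of -1.28 at percentile 0.05. Tap1, the peptide transporter, was at 59.1 and 18.6 CPM and the immunoproteasome subunit Psmb9 at 35.6 and 13.1 CPM.

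Genes of the TGF-beta pathway and matrix proteases were higher in Epcam-negative cells. Of 11 TGF-beta genes 10 were higher in Epcam-negative cells, 7 by 2-fold or more, with a median of 1.70 at percentile 100. The matricellular gene Ccn2 was at 36.4 and 421 CPM and the ligand Tgfb2 at 15.5 and 109.7 CPM, whereas Tgfbi, a secreted adhesion protein, was at 492.5 and 153.2 CPM. Of 11 matrix proteases and inhibitors 10 were higher in Epcam-negative cells, 7 by 2-fold or more, with a median of 1.77 at percentile 99.98. The stromelysin gene Mmp3 was at 491 and 6650.0 CPM, the protease inhibitor Timp2 at 154.1 and 1649 CPM and the collagenase Mmp13 at 205.3 and 1751 CPM, while the gelatinase Mmp9 was at 245.6 and 42.8 CPM. These levels rest on few cells: without the Epcam-positive cell with most of its reads Mmp3 was at 216.1 CPM and Mmp13 at 110.8 CPM there, and 3 cells held 51.2% and 50.3% of their Epcam-negative reads. Without the Epcam-negative cell with most of its reads Mmp9 was at 16.15 CPM there. Mmp3, Mmp10 and Mmp13 lie on the part of chromosome 9 where 20 of 23 measured protein-coding genes were 2-fold or more higher in Epcam-negative cells.

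Inflammatory mediators were divided between the populations. Of 15, 9 were 2-fold or more higher in Epcam-negative cells and 4 in Epcam-positive cells, with a median of 1.54 at percentile 100. The monocyte chemokine Ccl7 was at 30.8 and 748 CPM, the macrophage growth factor Csf1 at 7.85 and 127.7 CPM, and Il6 at 17.9 and 182.6 CPM, where 1 cell held 63.1% of the Epcam-positive reads and the level without it was 6.80 CPM. The alarmin Il1a was at 267.3 and 20.3 CPM, the calprotectin chains S100a8 and S100a9 at 364 and 143.7 CPM in Epcam-positive and 38.05 and 14.4 CPM in Epcam-negative cells, and the chemokine Ccl20 at 15.9 and 5.05 CPM, with the opposite direction in plate columns 1 to 12 (1.58) and reads in only 6 Epcam-positive and 3 Epcam-negative cells. Without the cell with most of its reads, Il1a was at 9.31 CPM and Ifit1 at 7.77 CPM in Epcam-negative cells, S100a8 at 224.2 CPM in Epcam-positive cells, and Ccl20 at 6.71 CPM in Epcam-positive or 0.656 CPM in Epcam-negative cells. Of 7 interferon-responsive genes 5 were 2-fold or more higher in Epcam-negative cells, with a median of 1.56 at percentile 99.6. Without the Epcam-negative cell with most of its reads, Usp18, which sits at that median, had 0.96 and Irf7 0.80. In the same way Ifit1 had 3.08, Bst2 2.35 and Isg15 1.77. Ifit1 had 1 read in Epcam-positive cells and was at 20.03 CPM in Epcam-negative cells, a log2 ratio of 4.34 (4.10 to 4.39), with 61.4% of its Epcam-negative reads in 1 cell, and Bst2 was at 4.55 and 31.4 CPM. Of 14 immediate early genes, which respond to dissociation among other stimuli, 11 were higher in Epcam-negative cells and 4 by 2-fold or more, with a median of 0.64 at percentile 99.2, which turned to -0.50 with the 50-cell well in place of the Epcam-negative cells. Egr1 was at 431 and 1348 CPM, and Btg2 at 366 and 814 CPM with -0.40 in the 50-cell well.

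Lineage, Wnt and metabolic lists were mixed. The median of 9 hair follicle genes was -0.39 at percentile 15.8. Nfatc1 was at 22.1 and 174.6 CPM and Tcf7l1 at 6.64 and 19.6 CPM, both factors of hair follicle stem cells, while Lhx2, another such factor, was at 21.4 and 6.44 CPM and the surface gene Cd200 at 272.9 and 126.3 CPM. The median of 4 Wnt response genes was -0.94 at percentile 2.73, but the same genes had 0.13 in plate columns 1 to 12 and -0.79 in columns 13 to 24. Wif1, a Wnt inhibitor, was at 53.6 and 12.5 CPM, with the opposite direction in plate columns 1 to 12 (1.28), and 90.3% of its Epcam-positive and 71.1% of its Epcam-negative reads lay in 3 cells of each population. Tcf7, a Wnt effector, was at 27.2 and 10.8 CPM, and Notum, which inactivates Wnt proteins, at 5.68 and 14.1 CPM. Without the cell with most reads in a population, Wif1 was at 33.8 CPM in Epcam-positive and 7.31 CPM in Epcam-negative cells, and Notum at 3.05 CPM in Epcam-positive cells. The median of 12 hypoxia and glycolysis genes was -0.47 at percentile 6.96. The glucose transporter Slc2a1 was at 971.5 and 315.5 CPM and lactate dehydrogenase Ldha at 3434 and 1578 CPM, whereas the hexokinase Hk2 was at 100.96 and 226.01 CPM.

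Markers of other cell types were few, apart from genes shared with mesenchymal cells. Ptprc, the pan-leukocyte CD45, had a thinned read in 0 of 62 Epcam-positive and 1 of the Epcam-negative cells. Of 13 immune markers 3 were measured, with a median of -0.86 at percentile 8.91, which turned to 0.09 over all 13. Cd74, the MHC class II invariant chain, was at 30.15 and 3.97 CPM, with 94.8% of the Epcam-negative reads in 1 cell and 0.206 CPM without it, Cd68 at 15.3 and 7.99 CPM, and Cd14 at 7.41 and 16.2 CPM. The endothelial marker Pecam1 was at 13.3 and 4.60 CPM, and no melanocyte or erythroid marker was measured. The pericyte marker Rgs5 had 0 reads in Epcam-positive cells and was at 13.2 CPM in Epcam-negative cells. By counting error only, Rgs5 was at least 109.6-fold higher there, but 94.6% of its reads lay in 3 cells, so this is no bound between the populations. Without the cell with most of them it was at 7.05 CPM. Of 7 genes on the normal dermal fibroblast list 6 were 2-fold or more higher in Epcam-negative cells, with a median of 5.46 at percentile 100. Dpt, a dermal matrix protein with 3 reads in Epcam-positive cells, had a log2 ratio of 6.75 (6.48 to 6.88), Mfap5, a microfibril protein, was at 2.58 and 353.5 CPM (1.02 CPM without 1 Epcam-positive cell), and Ly6c1 at 327 and 77.4 CPM. Dcn and Lum of that list are also on the matrix list, and the sort for YFP would remove stromal cells without recombination.

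Clustering of the kept cells gave 4 clusters, which serve as a description and not as a comparison. Of the 10 genes with the highest ratios per cluster, some present in over 50% of its cells are named for each. Cluster 0 had Krt17, Epcam and Lypd3 and held 60 Epcam-positive and 18 Epcam-negative cells. Cluster 1 had Aqp5, H19 and Cdh13 (2 and 83 cells), cluster 2 had Eln, Col14a1 and Sfrp2 (78 Epcam-negative cells), and cluster 3 had Cfap300, Ankrd1 and Akap12 (84 Epcam-negative cells). Cfap300 was present in 91.7% of the cells of cluster 3, and lies on the part of chromosome 9 named above, as do Cep126 (39.3%) and Msantd4 (36.9%) of its 10 genes. Resolution 1.0 gave 9 clusters.

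The well with 50 Epcam-negative cells held 154897 gene reads. Epcam had 0 reads there, which allows up to 23.8 CPM, and Cdh1 also had 0. Krt14 was at 1595 CPM, Vim at 6649.6 CPM, Col1a1 at 2376 CPM, Vcam1 at 103.3 CPM, Itgav at 238.9 CPM and Itgb3 at 12.9 CPM. Across 9574 genes, which are not independent replicates, the well had a Pearson correlation of 0.796 with Epcam-negative and 0.607 with Epcam-positive cells (Spearman 0.815 and 0.644). The Epcam-negative well set up with 0 cells held 4018 gene reads, with Vim at 25 reads, Krt14 at 4 and Epcam at 0, and the Epcam-positive well set up with 0 cells held 99241 gene reads, with Krt14 at 896 reads and Epcam at 69.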

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

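All tests in this part and their criteria were chosen only after the result was seen, with an exception. Criteria for the share of cells with Krt14 and Vim without cluster 0 were set down before that share was known. Leaving out those cells was nevertheless added after the data were seen.

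Reads were present in wells outside the comparisons, which were set up with no cell. The Epcam-negative well with 0 cells held 4018 gene reads beside 12860 spike-in reads, with Sparc at 26 reads and Vim at 25 reads. The Epcam-positive well with 0 cells held 99241 gene reads beside 8230 spike-in reads, with Epcam at 695 CPM, Krt14 at 9029 CPM and Col1a1 at 1 read.

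Index swapping at the rate of the Epcam-negative well with 0 cells (0.0284% of the reads of the 37 wells that share an index with it) would give the Epcam-positive well 3906 reads, and it held 25.4 times as many. Sorted cells stay open, since its 12.1 gene reads per spike-in read lie below the lowest kept Epcam-positive cell (18.1) but within the labelled Epcam-positive cells, which went down to 0.428, and its 8248 genes lie above at most 7221 in Epcam-positive and 8138 in Epcam-negative single cells drawn to 99241 reads. A trace of RNA or cDNA from many Epcam-positive cells may also account for the reads and cannot be told apart from sorted cells, since across genes the well correlated with Epcam-positive cells at 0.756 and with Epcam-negative cells at 0.602 (Pearson). At 5.45% of the median RNA per spike-in read of Epcam-positive cells, such a trace could reach other wells too, which was not tested well by well. No biological explanation was tested.

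Krt14 reads in Epcam-negative cells were a result that a background of Epcam-positive RNA could give: of 260 genes with at least 500 CPM in Epcam-positive cells, Epcam was the scarcest in Epcam-negative cells relative to its Epcam-positive level, and it allows at most 2.24% of Epcam-positive RNA, or 16.4% of the Krt14 CPM, so that up to this part of the summed Krt14 reads stays open to carry-over. Outside clusters shared with Epcam-positive cells, carry-over as the main source of the summed reads is argued against by bounds on the Krt14 CPM. The bound was 2.32% without the 18 cells of cluster 0, which Epcam helped to set apart. Without 19 cells of a clustering made without these 260 genes, bounds were 3.90% (from Ly6d) and 27.7% (from Epcam). All these bounds take carry-over as drawn alike from all Epcam-positive cells. Ly6d was present in only 42.3% of the cells of cluster 0. Cell by cell carry-over stays open. Krt17 reads held it to at most 50% of the Krt14 reads in only 39.5% of the Epcam-negative cells with Krt14 (31.04% to 48.5%). Epcam-positive cells in Epcam-negative wells are argued against by the share of cells with Krt14 and Vim, which was 45.3% without the 18 cells of cluster 0, and 38.97% with 1000 variable genes in the clustering, whereas doublets with an Epcam-positive cell stay open for a part, since Epcam was present in 6.45% of the cells with both (2.83% to 12.3%). Krt14 expression in part of the Epcam-negative tumour cells stays open beside carry-over in single cells. Misplaced Epcam-positive cells and doublets stay open too, and population cannot be told apart from plate row.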

How the results depend on the processing

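Leaving out the Epcam-negative cells of cluster 0 or the Epcam-positive cell with most Col1a1 reads, and clustering without the genes at the start of chromosome 9 or without those of at least 500 CPM in Epcam-positive cells, were the alternatives chosen after the data were seen. No paired analysis was possible because the labels name no animal. Over 14 alternatives, 344 of 347 values of the list medians kept their direction, as did 1519 of 1534 values of the named genes over 13 alternatives. Part of the agreement among named genes was fixed by construction. A pseudocount cannot change the direction of a gene's ratio. Genes named beyond the lists were also chosen for the same direction in both sets of plate columns. These counts are therefore no measure of how stable the directions are. The epithelial median (-2.86) was -3.09 with the stricter cell filter, -2.80 with the mean of each cell's CPM, -2.72 with TMM, -2.75 with median-of-ratios and -3.20 with spike-in scaling, -2.28 with a pseudocount of 10 CPM, -3.16 in plate columns 1 to 12, -2.46 in columns 13 to 24, -3.06 with the 50-cell well, -2.49 without the filter on low members and -3.90 without the cells of cluster 0. The mesenchymal median (4.46) was 4.12 with spike-in scaling, 5.18 and 3.28 with pseudocounts of 0.1 and 10 CPM, 4.15 with the 50-cell well and 4.13 without the filter on low members. The share of Epcam-negative cells with Krt14 and Vim (47.1%) was 82.9% at 1 read, 33.5% at 20 reads, 99.6% at 1 read without thinning and 40.7% in columns 13 to 24, and that of Epcam-positive cells (48.4%) was 80.6%, 35.5% and 95.2% under the 3 presence rules. The share with none of Itgav, Itgb3 and Vcam1 (22.8%) was 6.84%, 57.8% and 4.18% under the same rules. The RNA content ratio (0.711) was 0.784 from summed reads, 0.663 with no cell filter, 0.765 with the stricter filter, 0.717 without mitochondrial genes, 0.637 in columns 1 to 12, 0.774 in columns 13 to 24 and 0.716 without the cells of cluster 0. Resolution 1.0 gave 9 clusters in place of 4, resolution 0.2 gave 3 and 1000 variable genes gave 5. Clustering without the genes at the start of chromosome 9 gave 5, of which 2 held 14 and 17 Epcam-negative cells beside 50 and 10 Epcam-positive cells, where cluster 0 held 18 beside 60, and clustering without the genes of at least 500 CPM also gave 5. With 1000 variable genes such clusters held 12 and 38 Epcam-negative cells, so the cells left out with cluster 0 depend on the clustering. In columns 1 to 12, the 4 members of the Wnt response list had a median of 0.13 in place of -0.94, against -0.63 when members were chosen again there and 3 were left. In those columns, Ccl20 (1.58) and Wif1 (1.28) had the opposite direction. With the 50-cell well in place of the Epcam-negative cells, the list immediate early and dissociation response (-0.50), Btg2 (-0.40), Sprr1b (1.38) and Sprr2d (3.12) had the opposite direction. The values of Bst2 (-2.47), Cd14 (-3.07), Cdh2 (-0.11), Isg15 (-2.86), Lum (-0.26), Notum (-2.74), Snai1 (-0.79) and Rgs5 (0) come from 0 reads in the well, which allow up to 23.8 CPM, above their Epcam-positive levels, so they show no change of direction. The Epcam-negative levels of Lum (89.4 CPM), Snai1 (58.5 CPM), Bst2 (31.4 CPM), Cdh2 (30.1 CPM) and Isg15 (28.2 CPM) lie above that limit, so in the well these genes were below the kept Epcam-negative cells. Usp18 (-0.21) had 1 read there, as had both members left of the interferon list (-1.47), which decides as little. The list immune cells turned to 0.09 without the filter on low members. Apart from the presence rules, pseudocounts and scalings, whose construction moves the values, the cause was not tested. The median of 9574 genes was -0.08 as reported, 0.05 with TMM, 0.03 with median-of-ratios, -0.42 with spike-in scaling and -0.73 with the 50-cell well, so ratios under those settings are relative to these shifts. Depth limits genes at few reads: in the 154897 gene reads of the 50-cell well, a gene with 0 reads can be as high as 23.8 CPM, and 0 of 62 cells allows a share of up to 5.78%.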

Other observations

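The tests of chance, of the mesenchymal state and of a regional gain for chromosome 9, and their criteria, were chosen only after the result was seen, and the clustering without those genes was added then.

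Genes at the start of chromosome 9 were higher in Epcam-negative cells as neighbours, and were singled out after their values were seen. Yap1, the transcriptional co-activator of the Hippo pathway, was at 109.2 CPM in Epcam-positive and 1025.5 CPM in Epcam-negative cells. Birc2 and Birc3, inhibitors of apoptosis beside it, were at 24.8 and 659.7 CPM and at 33.4 and 637 CPM, and the membrane protein gene Tmem123 was at 250.3 and 3236 CPM. Between 3335140 and 9239101, 22 of 23 measured protein-coding genes were higher in Epcam-negative cells and 20 were 2-fold or more higher, with a median log2 ratio of 2.48. Mmp1b (-0.74), Mmp12 (0.09) and Casp1 (0.28) were the exceptions to 2-fold, and Mmp1a (0.88), annotated as a polymorphic pseudogene, was not counted. The 23 measured genes beyond, from 13246955 to 20666584, had a median of 0.04, and 2 were 2-fold or more higher. The 50-cell well gave a median of 2.59 for the region over Epcam-positive cells, with 17 genes 2-fold or more higher. The 13 genes outside the Mmp, Birc and Casp families were all 2-fold or more higher, with a median of 3.09.

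Among 9162 windows of 10 neighbouring genes, the highest median was 3.45, on chromosome 9 from 7344381 to 8134294. The highest window elsewhere had 2.24, on chromosome X. The lowest window had -3.46, on chromosome 11 from 99065678 to 100261029 (Tns4 to Krt17), so a median of this size was not confined to chromosome 9. In 100 shuffles of gene order the highest window reached 3.10, which argues against chance. The mesenchymal state in general is argued against by a region median of 2.28 between clusters 2 and 3 of a clustering made without these genes. The mesenchymal lists were at -0.80 between them. This pair was picked for the largest region difference among pairs whose mesenchymal lists differed by under 1. Cluster 3 over 4 had -1.91 for the region and -0.32 for the lists, and cluster 2 over 4 had 0.14 and -1.12. In that clustering Yap1 was at 1918 CPM in cluster 2, 103.7 CPM in cluster 3 and 1026.5 CPM in cluster 4. Vim was at 6412, 6405 and 5067 CPM. A gain of the region in part of the Epcam-negative cells stays open, with 86.96% of its genes 2-fold or more higher but a median of 0.68 for the genes beyond it between clusters 2 and 3, and DNA was not analysed here, so shared regulation of neighbours stays open too.

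A hypothesis was that cells with more Yap1 show more activity of YAP, read from a list of its known target genes. Between the clusters with the highest and the lowest Yap1 level the median log2 ratio of 20 measured targets was 0.23, at percentile 61.6 of random lists whose middle was 0.18. Set down before the result was that more activity would put the median well above that of the random lists. The difference was 0.06, under the limit set beforehand for no such rise, so the list's median lay close to that of the random lists. Of the 20 targets, 13 were higher in the cluster with the highest Yap1. Targets were not left out of the clustering, so whether YAP activity rose with Yap1 cannot be told. Single targets went both ways, and activity through a part of them stays open. Ankrd1 was at 11.0 and 353.9 CPM and Amotl2 at 18.4 and 121.3 CPM in the lowest and highest cluster. Igfbp3 was at 282.4 and 22.5 CPM and Tgfb2 at 151.3 and 59.1 CPM there. Of the targets, 4 were 2-fold or more higher and 5 were 2-fold or more lower. Between the sorted populations, 21 measured targets had a median of 0.75, at percentile 99.99.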
